A study of Mus musculus with 2 samples.

How the data were processed

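Cortices of 4-month-old male Fam69c wild-type and knockout mice were pooled by genotype and dissociated, the cells were stained with 7-AAD and sorted, and 1 library per genotype was made with the 10x Genomics 3' v3.1 chemistry. The labels name 7 mice and leave open whether this is the number per genotype, and they give 13 or 12 indexing cycles without saying which library had which. The deposited tables hold raw UMI counts per gene and barcode, made with Cell Ranger 4.0.0 per the file headers and the submitters' processing notes, with no normalization. The notes also name mm10, Seurat 3.0 and R 4.0.3. The deposited barcodes had been called as cells before deposit, the lowest with 500 UMIs, and the annotation release is not given in the sources used here. The tables hold 32285 genes. Gene positions and lengths were taken from GENCODE M21 by gene identifier, which matched 99.6% of the genes.

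Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept. This removed 1998 of 7150 wild-type barcodes (27.9%) and 1702 of 9182 knockout barcodes (18.5%). Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0 wild-type and 164 knockout cells and was taken as having failed, so the highest-scoring cells were called at a rate of 0.8% per 1000 barcodes. This removed 212 wild-type cells (4.11%) and 448 knockout cells (5.99%) and was chosen after the automatic calls were seen. Both libraries were then clustered together, with no batch correction because library and genotype coincide. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were taken among those seen in at least 20 cells, without the Fam69 family, Xist and ribosomal protein, mitochondrial, hemoglobin, immediate early and heat shock genes. The clustering used 30 principal components (scikit-learn 1.9.0), 15 nearest neighbours and Leiden resolution 1 (leidenalg 0.10.2), with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

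The 34 clusters were named from markers of 20 cell types fixed before the data were examined. Each cluster was scored on the mean scaled level of each type's markers. A name needed a score of at least 0.7, a lead of at least 0.1 over the next type and at least 3 markers detected in 20% of cells. It also needed no larger number of another type's markers than of its own among the 10 genes with the highest fold, after genes detected about equally in every cluster were set aside. A cluster with under a 3rd of its library's median UMIs also needed at least 1 of its own markers among those 10. These scoring thresholds were set after the data were seen, and 11 clusters stayed unnamed. Some named clusters were led by genes outside their type, such as oligodendrocyte-like cluster 25 by hemoglobin and neuroblast-like cluster 12 by cell cycle genes.

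Raw UMIs were summed per library and class and scaled to CPM of the class total, with exact Poisson 95% intervals. Ratios of the libraries have exact conditional binomial intervals, and shares of cells have exact Clopper-Pearson intervals. A count of 0 is given with the level that 3 UMIs would make. All of these cover counting error only. Log2 ratios of genes are given without a pseudocount, except where genes are compared between settings, which has 10 CPM added on both sides. With 1 library per genotype no test was made, and no p-value or number of changed genes was drawn from cells. The main comparisons cover classes with at least 200 cells in each library, of which there were 3, and 2 smaller classes, neuroblast-like and endothelial-like cells, were added after the cell numbers were seen and are described in the closing section. Named genes were fixed by a rule before the data were examined. They are the 12 highest and 12 lowest ratios in the largest class and 6 each in the others, after adding 10 CPM on both sides. Genes needed at least 100 UMIs in the class and 50 CPM in a library, and were left out as possible free RNA when another named class of the library where the gene was higher held over 10 times the level. In each described list, up to 4 members with the largest ratios and the 3 most abundant members could be named.

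The 31 gene lists were fixed before the data were examined. The median log2 ratio of members with at least 50 UMIs, again with 10 CPM added, was placed among 10000 random lists of the same size drawn from 20 expression bins. The spread of a list median was taken by resampling its members. Later lists of glucocorticoid targets and clock genes, chosen after the gene levels were seen, are used in the closing section alone. Trends with gene length were removed as the median of 20 length bins.

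The interval and list steps were run on simulated counts with known changes in 200 genes, 50 at each size. The counts were Poisson draws from 1 pooled profile per class, which is the model behind the intervals, so coverage near 95% follows from the design. They check the calculation only. Variation between cells, genes that vary together and trends between libraries were not simulated. In astrocyte-like cells the interval held the true value for 95.7% of 12993 unchanged genes, and the median estimates for true log2 ratios of -1, -0.5, 0.5 and 1 were -1.02, -0.50, 0.50 and 0.99. In oligodendrocyte-like cells it held for 95.4% of 10047 genes, with estimates of -1.01, -0.48, 0.53 and 1.00. In microglia-like cells it held for 95.8% of 7090 genes, with estimates of -0.98, -0.48, 0.53 and 1.01. Of 200 unchanged lists per class, 3.5%, 5% and 2.5% fell outside the random range in the order above, and a list of 15 changed genes lay at percentile 100 in each.

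Alternatives fixed beforehand were no filter on cells, a filter of at least 1000 genes and at most 10% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.5 and 2, 3000 variable genes, and classes from each cell's own marker score. For levels they were a trimmed-mean (TMM) factor, a median-ratio factor, a total without mitochondrial and ribosomal protein genes, each cell weighed the same, cells thinned to 1 depth, and a pseudocount of 1 CPM. For lists they were all detected members and members with at least 200 UMIs. Thinning used the depth at the 10th percentile of each class: 1902, 7556 and 916 UMIs in astrocyte-like, oligodendrocyte-like and microglia-like cells, leaving out 374 and 275, 43 and 88, and 5 and 52 wild-type and knockout cells. Alternatives added after the data were seen were cells with at least 5000 UMIs, the gene-length trend removed, and astrocyte-like clusters 1 and 2 each alone. No data column of the files used here was left out. The levels of some single genes are not reported here.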

Results

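Single-cell RNA sequencing of dissociated cortex from 4-month-old male mice compared 1 wild-type library with 1 Fam69c knockout library, each made from cortices pooled by genotype. There was no replicate library, so no test was made, and genotype could not be separated from pool. The intervals given are exact 95% intervals that cover counting error only. The wild-type library held 7150 barcodes and 57166105 unique molecular identifiers (UMIs, which count captured transcripts), with a median of 4358 UMIs per barcode. The knockout library held 9182 barcodes and 75473717 UMIs, with a median of 7699. After filtering, 4940 wild-type and 7032 knockout cells remained. Their median UMIs per cell were 8580 and 8449, their median numbers of genes 2934 and 2980.5, and their median mitochondrial shares 3.98% and 4.34%. Gene levels are UMIs scaled to the class total (CPM), and log2 ratios are knockout over wild type.

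The first comparison asked how the transcript of the targeted gene differed between the libraries. Fam69c encodes a transmembrane kinase-like protein of the endoplasmic reticulum, and the files list it as Dipk1c (ENSMUSG00000047992), on the plus strand of chromosome 18 at 84719236 to 84740436 (GRCm38/mm10). Dipk1c was found mainly in astrocyte-like cells, where its level was 60.1 CPM in the wild-type library (57.0 to 63.3, 1430 UMIs) and 33.9 in the knockout library (32.0 to 35.9, 1185 UMIs), a ratio of 0.563 (0.521 to 0.609). Among 3496 ranked genes of this class it had the 24th lowest ratio. It was lower in the knockout library in each of the 4 astrocyte-like clusters: 56.3 against 33.5 in cluster 1, 62.0 against 36.0 in cluster 2, 51.4 against 32.2 in cluster 3 and 51.2 against 23.7 in cluster 5. Over all cells the levels were 32.3 and 20.6. Oligodendrocyte-like cells held 0.708 CPM in the wild-type and 0.421 in the knockout library, and microglia-like cells 0.667 and 1.41, each from 6 or fewer UMIs. Of the related genes in astrocyte-like cells, Dipk1a was 7.57 and 9.18, Dipk1b 36.8 and 43.2, and Dipk2a 11.8 and 8.46 in the wild-type and knockout libraries. Dipk2b had 0 UMIs in both, where 3 UMIs would make 0.126 and 0.0857 CPM. The assay reads 3' ends and the deleted part of the gene is not given in the sources used here, so the remaining Dipk1c UMIs neither establish nor exclude a loss of the intact transcript.

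**Figure D1:**
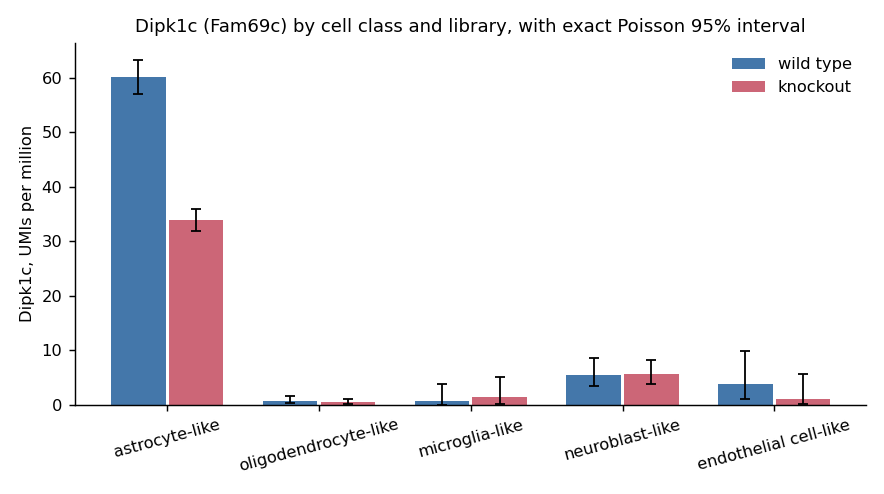
Level of Dipk1c (Fam69c) in CPM for 5 cell classes, with 1 bar per library and the exact Poisson 95% interval as the error bar. The astrocyte-like level was 60.1 in the wild-type and 33.9 in the knockout library.

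The second comparison asked how the cell classes were represented in each library. Astrocyte-like cells were the largest class in both, with 46.9% of wild-type cells (exact binomial interval 45.5 to 48.3%) and 59.4% of knockout cells (58.2 to 60.5%). Oligodendrocyte-like cells made up 11.1% (10.3 to 12.0%) and 10.8% (10.1 to 11.5%), and microglia-like cells 5.06% (4.47 to 5.71%) and 4.56% (4.09 to 5.08%). Neuroblast-like cells were 3.97% and 4.88%, and endothelial-like cells 3.42% and 3.73%. Among leukocyte-like classes, monocyte-like cells were 0.486% (0.312 to 0.722%) of the wild-type and 1.01% (0.789 to 1.27%) of the knockout library. Neutrophil-like cells were 1.28% and 1.69%, T cell-like cells 1.40% and 1.51%, B cell-like cells 1.58% and 1.22%, and NK cell-like cells 0.425% and 0.398%. Oligodendrocyte precursor-like cells were 1.52% (1.20 to 1.90%) and 0.654% (0.479 to 0.872%), and erythrocyte-like cells 2.85% (2.41 to 3.36%) and 0.782% (0.590 to 1.02%). Dendritic cell-like cells were 1.48% and 0.825%, with median UMIs of 1419 in the wild-type and 13078 in the knockout library. Pericyte-like cells were 0.85% and 0.939%, ependymal-like cells 0.304% and 0.356%, and fibroblast-like cells 0.0607% (3 cells) and 0.213% (15 cells).

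Unnamed clusters held 17.3% (16.3 to 18.4%) of wild-type cells, with a median of 1332 UMIs, and 7.08% (6.49 to 7.71%) of knockout cells, with a median of 4366, under naming thresholds set after the data were seen. The shares may also depend on a sort with the dye 7-AAD, which marks dying cells, and on the depth gap between the libraries. Neither was tested for shares. They did depend on the quality filters, which removed 27.9% of wild-type and 18.5% of knockout barcodes. The log2 ratio of the astrocyte-like share, 0.34, ranged from 0.13 with fewer clusters to 0.63 with each cell classed by its own markers. That of the oligodendrocyte-like share moved from -0.05 to -0.57 with no filter, to -0.39 with a stricter filter and to -0.69 with 3000 variable genes. For microglia-like cells, -0.15 became 0.13 with no filter and -0.47 with the stricter filter. The direction also turned for endothelial-like (0.12 to -0.41 with no filter), neutrophil-like (0.41 to -0.34 with no filter), neuroblast-like (0.30 to -0.07 with doublets kept), monocyte-like (1.06 to -0.10 with fewer clusters) and dendritic cell-like cells (-0.84 to 0.85 with more clusters). It turned as well for T cell-like (0.11 to -0.13) and pericyte-like cells (0.14 to -0.07) with the stricter filter, NK cell-like cells (-0.09 to 0.15) with no filter and ependymal-like cells (0.23 to -0.44) with each cell classed by its own markers. The erythrocyte-like ratio moved from -1.87 to -0.03 with no filter, the oligodendrocyte precursor-like ratio from -1.21 to -0.11 with each cell classed by its own markers, and the unnamed ratio from -1.29 to -0.50 with no filter, -0.43 with the stricter filter and -0.23 with fewer clusters.

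**Figure D2:**
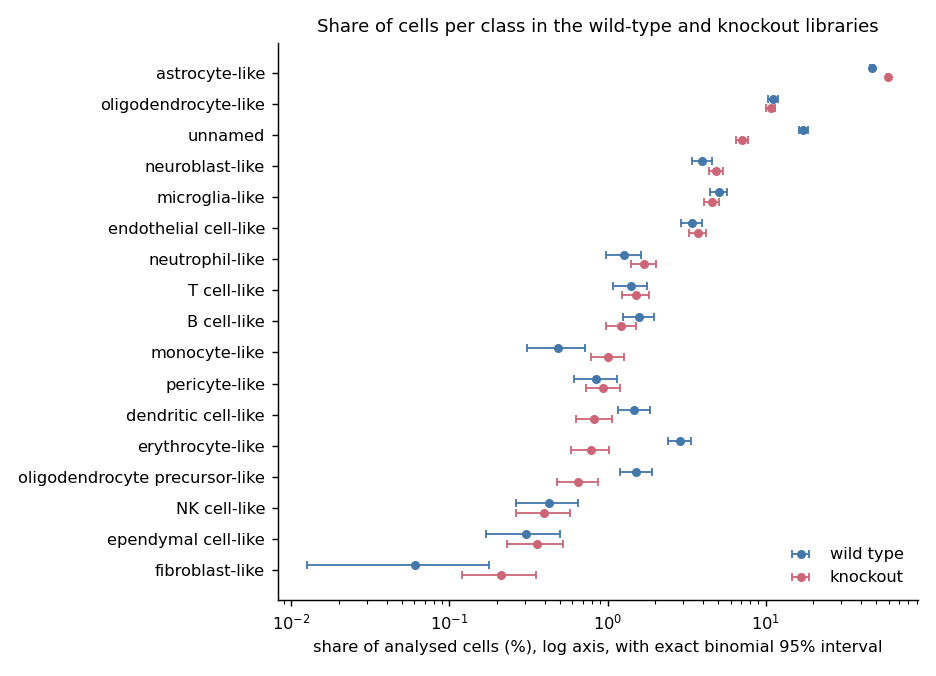
Share of analysed cells per class on a log axis, with 1 point per library and the exact binomial 95% interval. Astrocyte-like cells were 46.9% of the wild-type and 59.4% of the knockout library, and unnamed cells 17.3% and 7.08%.

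The third comparison asked which genes differed in level within astrocyte-like cells (2316 wild-type and 4175 knockout cells, median UMIs 11039.5 and 8737). Metallothioneins, which bind zinc and copper, were higher in the knockout library. Mt2 was 571 CPM in the wild-type and 1410 in the knockout library (log2 1.30, 1.28 to 1.33), Mt1 3794 and 8778 (log2 1.21, 1.20 to 1.22), and Mt3 3520 and 5692 (log2 0.69, 0.68 to 0.70). Also among the 12 highest ratios were Cst3, which encodes the secreted protease inhibitor cystatin C (9483 and 15499), Thrsp, a lipogenic factor (231 and 394), the stress-response gene Gadd45g (44.7 and 94.3) and the kinesin gene Kifc3 (51.1 and 114). Sult1a1, Mrpl41, 1190005I06Rik, Ppdpf and Selenom completed that group, with log2 ratios of 0.92, 0.85, 0.79, 0.78 and 0.75. Among the 12 lowest ratios were mt-Nd6, a mitochondrially encoded subunit of complex I (140 and 57.2, log2 -1.29, -1.37 to -1.21), the imprinted noncoding RNA Kcnq1ot1 (375 and 178, log2 -1.07), the nuclear envelope gene Syne1 (595 and 318, log2 -0.90), the ubiquitin ligase gene Trim9 (601 and 331, log2 -0.86) and the growth factor receptor gene Egfr (182 and 104, log2 -0.81). The others were Gm17167, AY036118, Gm42418, D10Wsu102e, Arhgef12, Vps37a and Rbm28, with log2 ratios of -1.42, -1.03, -0.92, -1.09, -0.82, -0.86 and -0.85. AY036118 lies within the span of Gm42418 on chromosome 17, so these may not be separate differences.

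Lists of genes fixed before the data were examined were compared with 10000 random lists matched on expression, as a description of these libraries. Of 30 lists measured in astrocyte-like cells, 4 had a median log2 ratio above and 2 a median below the range of the central 95% of the random lists. If the lists held unrelated genes, 1.5 would fall outside by chance. All 25 nuclear-encoded genes of oxidative phosphorylation were higher in the knockout library, with a median of 0.38 (percentile 100). Examples are the respiratory chain subunit genes Ndufa13 (319 and 440 CPM), Cox4i1 (592 and 810) and Cox8a (953 and 1270). All 30 ribosomal protein genes were also higher, with a median of 0.31 (percentile 99.5), such as Rpl11 (299 and 408), and 24 of them met the criterion for possible free RNA. Heat shock genes had a median of 0.16 (9 of 12 higher, percentile 97.6), with the chaperone genes Hspe1 at 232 and 309 and Hsph1 at 36.8 and 28.1. Cell cycle genes had a median of 0.12 (9 of 10 higher, percentile 99.9), and all 10 met the criterion for possible free RNA. Of 18 genes of stress granule proteins, RNA-binding factors that gather untranslated messages, 14 were lower in the knockout library, with a median of -0.25 (percentile 0.830). They included Tia1 (287 and 224), Caprin1 (129 and 100.4), Atxn2l (103 and 76.9) and Fmr1 (90.6 and 69.5), while Eif4a1 was higher (153 and 192). Lists of the integrated stress response (median 0.02, percentile 72.2), of endoplasmic reticulum chaperones (0.15, 87.0) and of eIF2 kinases and factors (-0.08, 46.6) lay within the random range. So did genes of homeostatic (-0.14, 5.46) and reactive astrocytes (0.05, 96.6), the latter including Vim (43.1 and 67.8) and Gfap (25.4 and 31.6). Of the 10 reactive astrocyte genes measured, 8 met the criterion for possible free RNA. Gfap was lower in the knockout library in cluster 1 (40.1 and 33.6) and higher in clusters 2, 3 and 5. Hemoglobin genes, which astrocytes do not make in quantity, held 0.423% of the UMIs of this class in the wild-type and 0.158% in the knockout library, with a median of -1.30.

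Most wild-type astrocyte-like cells lay in cluster 2 (54.0%, against 21.1% of knockout cells), led by Trim9 and Slc1a2. Most knockout ones lay in cluster 1 (53.6%, against 9.63%), led by Mt1, Mt2 and Mt3. A cluster mostly from 1 library may be that library. Cluster 3 (18.4% and 17.8%), led by Syne1, had a median of 10.8% mitochondrial UMIs and median UMIs of 4656 and 3006. Cluster 5 had median UMIs of 1230 and 1842. Levels of mt-Nd6, Kcnq1ot1 and Syne1 were highest in cluster 3 in both libraries (325, 770 and 1496 CPM in the wild type). Each was lower in the knockout library in every astrocyte-like cluster. Whether cell quality bears on them was not tested. Within clusters 1 and 2 taken alone, the 12 highest and 12 lowest genes kept their direction, with log2 ratios in the order of the clusters of 0.83 and 0.88 for Mt1, 0.98 and 1.04 for Mt2, 0.40 and 0.33 for Mt3, 0.40 and 0.29 for Cst3, -0.26 and -0.44 for Kcnq1ot1, -0.34 and -0.38 for Syne1 and -0.56 and -0.52 for Trim9. The oxidative phosphorylation median was 0.08 and 0.07 there and the ribosomal protein median 0.07 and 0.08. With the same mix of clusters in both libraries the oxidative phosphorylation median was 0.09 (20 of 25 higher, percentile 96.93), within the random range, while with each cell weighed the same the ribosomal protein median was 0.04 and the cell cycle median 0.01. In this class the log2 ratios were lower for genes with a longer span (rank correlation -0.45) and a longer transcript (-0.60). The other classes compared showed the same trend. The correlations with span and transcript length were -0.38 and -0.49 in oligodendrocyte-like and -0.38 and -0.44 in microglia-like cells. They were -0.42 and -0.55 in neuroblast-like and -0.35 and -0.39 in endothelial-like cells. Without the trend with gene span, the ribosomal protein, heat shock and cell cycle medians of astrocyte-like cells (0.24, 0.07 and 0.10) lay within the random range. The stress granule median was -0.12 and still below it. Removal of the stronger transcript-length trend is not given for the stress granule list in any class. Genes with the longest transcripts had a median of -0.32 in astrocyte-like cells. Whether the stress granule difference goes beyond that trend stays open. The heat shock median was 0.03 with each cell weighed the same and turned to -0.00143 in cluster 1 alone. Scaling by trimmed means moved the median of all genes in this class by 0.10, so differences of that size depend on the scaling.

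**Figure D3:**
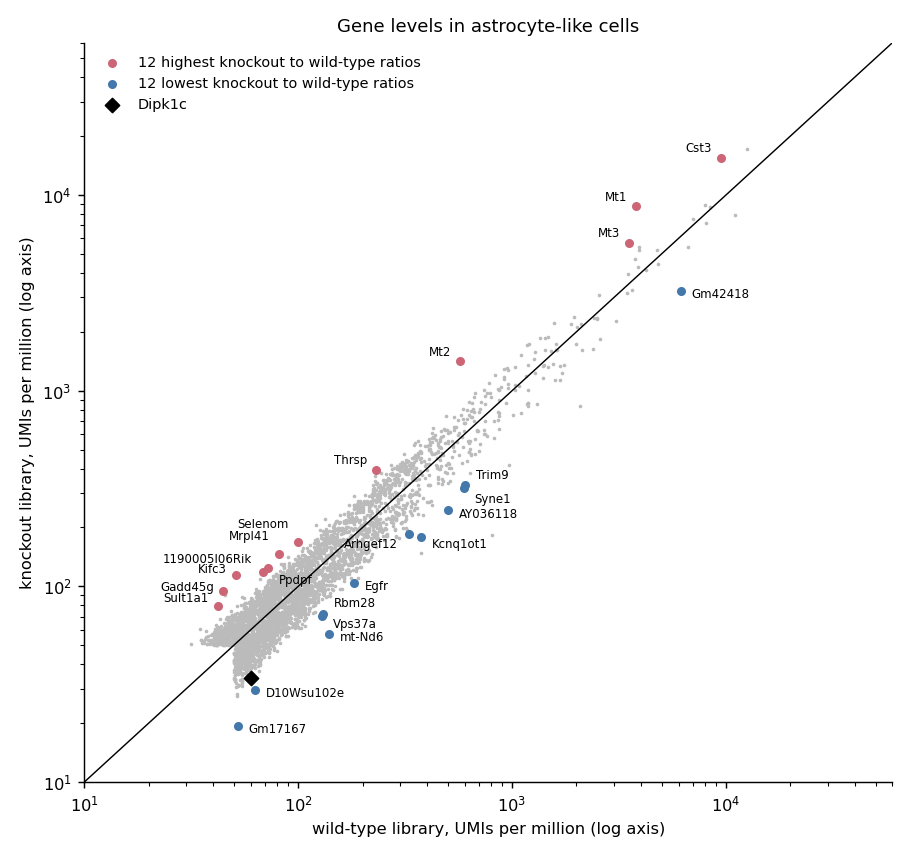
Gene levels in astrocyte-like cells in CPM, wild-type library on the x axis and knockout library on the y axis, both logarithmic; each grey point is a gene, the line marks equal levels, and coloured points are the 12 highest and 12 lowest ratios. Mt1 (3794 and 8778) and Mt2 (571 and 1410) lie above the line, and mt-Nd6 (140 and 57.2) and Dipk1c (60.1 and 33.9) below it.

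The fourth comparison covered oligodendrocyte-like cells (550 wild-type and 758 knockout cells, median UMIs 14346 and 11436). The kinase gene Sgk1, a classic glucocorticoid-induced gene, was 483 CPM in the wild-type and 861 in the knockout library (log2 0.84, 0.78 to 0.89), and Ddit4, an inhibitor of mTORC1 signalling, 72.4 and 129 (log2 0.83, 0.69 to 0.97). The actin-regulatory gene Marcksl1 was 81.9 and 162 (log2 0.98), and Tmem141, Ppdpf and Igsf8 had log2 ratios of 1.05, 0.82 and 0.74. Lower in the knockout library were the lipid transporter gene Abca8a (137 and 69.6, log2 -0.98), the spectrin gene Sptbn1 (493 and 279, log2 -0.82), the kinesin gene Kif21b (57.9 and 28.4, log2 -1.03), Cobl (72.3 and 36.6, log2 -0.98), Gm42756 (log2 -1.06) and mt-Nd6 (log2 -0.91). Of 29 lists, 6 had a median above and 3 a median below the random range, where 1.45 lists of unrelated genes would fall outside by chance. Endoplasmic reticulum chaperones were higher as a group (12 of 15, median 0.19, percentile 99.97), among them Hspa5 (294 and 355), Pdia6 (122 and 168), Sdf2l1 (43.8 and 57.8) and Manf (84.9 and 114). Cholesterol synthesis genes were likewise higher (12 of 15, median 0.19, percentile 100), including Sqle (50.9 and 77.5), Idi1 (118 and 165) and Hmgcs1 (309 and 419). Oxidative phosphorylation had a median of 0.20 (24 of 25 higher, percentile 100), while ribosomal proteins (0.13, 96.3), myelin genes (0.16, 95.6) and the integrated stress response (0.02, 78.8) lay within the range. Genes of the disease-associated oligodendrocyte state were lower (8 of 9, median -0.27, percentile 0.560), including complement C4b (30.5 and 18.3) and Serpina3n (8.38 and 4.52). Stress granule proteins were also lower (14 of 18, median -0.17, percentile 1.70), including Ddx3x (126 and 92.3) and Tial1 (106 and 81.9).

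Transcripts of other cell types had different shares in the libraries in this class, and background RNA was not measured. Astrocyte transcripts (30 genes) held 0.0870% of its UMIs in the wild-type and 0.162% in the knockout library, and hemoglobin 0.80% and 0.243%. The lists of homeostatic astrocyte genes (median 0.46, with 8 of 12 members possible free RNA), synapse genes (0.28, 5 of 7), activated endothelium (0.21, 3 of 3) and hemoglobin (-1.66) also consist largely of such transcripts. With 10 CPM added on both sides, Tmem141 moved from 0.90 to 0.38 with each cell weighed the same and to 0.36 at equal depth, and Igsf8 from 0.69 to 0.39 at equal depth. The disease-associated list moved to -0.12 with doublets kept, and its place among random lists in that setting is not given here. Without the gene-length trend, oxidative phosphorylation moved to 0.11, endoplasmic reticulum chaperones to 0.12 and stress granule proteins to -0.11. These last medians were all still outside the random range. The myelin median rose to 0.21 without the gene-length trend and then lay above that range (percentile 99.93). Without the trend with transcript length the oxidative phosphorylation median was 0.08 and within the range (percentile 95.57). The cholesterol synthesis median was 0.12 with each cell weighed the same. The homeostatic astrocyte median turned to -0.42, the synapse median to -0.02 and the activated endothelium median to -0.48 with no filter on cells.

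The fifth comparison covered microglia-like cells (250 wild-type and 321 knockout cells, median UMIs 6705.5 and 4898). The monocyte-attracting chemokine gene Ccl12 was 77.4 CPM in the wild-type (63.9 to 92.8) and 381 in the knockout library (349.8 to 415), a log2 ratio of 2.30 (2.01 to 2.60). Ccl2 was 24.7 and 98.7 (log2 2.00, 1.47 to 2.56), and Socs3, a feedback inhibitor of cytokine signalling, 184 and 530 (log2 1.53, 1.32 to 1.73). Gadd45g was 98.7 and 299 (log2 1.60), Ddit4 24.7 and 93.0 (log2 1.91) and the protease inhibitor gene Spint1 55.4 and 140 (log2 1.34). Lower in the knockout library were the histone genes Hist1h1c (711 and 245, log2 -1.54, -1.71 to -1.36) and Hist1h2bc (325 and 116, log2 -1.48), the metalloprotease gene Adamts1 (594 and 253, log2 -1.23), the immediate early gene Egr3 (85.4 and 24.7, log2 -1.79), Fam71a (log2 -1.95) and Gm15655 (log2 -1.79). Of 29 lists, 6 had a median above and 2 a median below the random range. Immediate early genes, which respond rapidly to stimulation, were lower as a group (14 of 20, median -0.19, percentile 0.550), including Fosb (233 and 128), Atf3 (1114 and 715) and Jun (6414 and 4887), with Socs3 as an exception. Ribosomal protein genes (30 of 30, median 0.30, percentile 99.99) and oxidative phosphorylation genes (24 of 25, median 0.37, percentile 100) were higher, for example Rpl13 (908 and 1271) and Cox5b (115 and 183). Complement genes lay just within the range (median 0.28, percentile 97.46), with C1qa at 6934 and 9654 and C5ar1 at 127 and 264. Cytokines and chemokines went both ways (9 of 16 higher, median 0.09, percentile 78.5), since Ccl3 (834 and 629) and Ccl4 (1555 and 712) were lower. Homeostatic (-0.10, 11.2) and disease-associated microglia genes (0.08, 57.5), the integrated stress response (0.12, 84.9) and stress granule proteins (-0.03, 36.7) lay within the range.

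Astrocyte transcripts made up 0.139% and 0.267% of the UMIs of this class and hemoglobin 2.37% and 0.284%. Possible free RNA was frequent among homeostatic astrocyte genes (0.69, 9 of 10 members possible free RNA), myelin (0.32, 7 of 7), cholesterol synthesis (0.27, 5 of 8) and hemoglobin genes (-2.93), while cell cycle genes (0.37) rested on 5 members and lay within the range without the gene-length trend (0.18). An unnamed cluster of 44 wild-type and 27 knockout cells, led by Ccl2 and Ccl7 and with 5 microglia markers among its 10 leading genes, lay outside this class. Its highest marker score was that of border macrophages (0.876, against 0.829 for microglia), and its median UMIs were 1603 and 1682. With doublets kept, Ccl2 turned from 1.65 to -0.52 (10 CPM added on both sides) and the immediate early median moved to -0.37, against -0.05 at equal depth; without the gene-length trend the immediate early, ribosomal protein and oxidative phosphorylation medians were -0.41, 0.09 and 0.22. With each cell classed by its own markers the cholesterol, homeostatic astrocyte and myelin medians turned to -0.17, -0.06 and -0.24, and oxidative phosphorylation moved to 0.21. With 10 CPM added likewise, Ccl2 was 1.07 with each cell weighed the same, and Egr3 moved from -1.46 to -3.43 at equal depth.

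**Figure D4:**
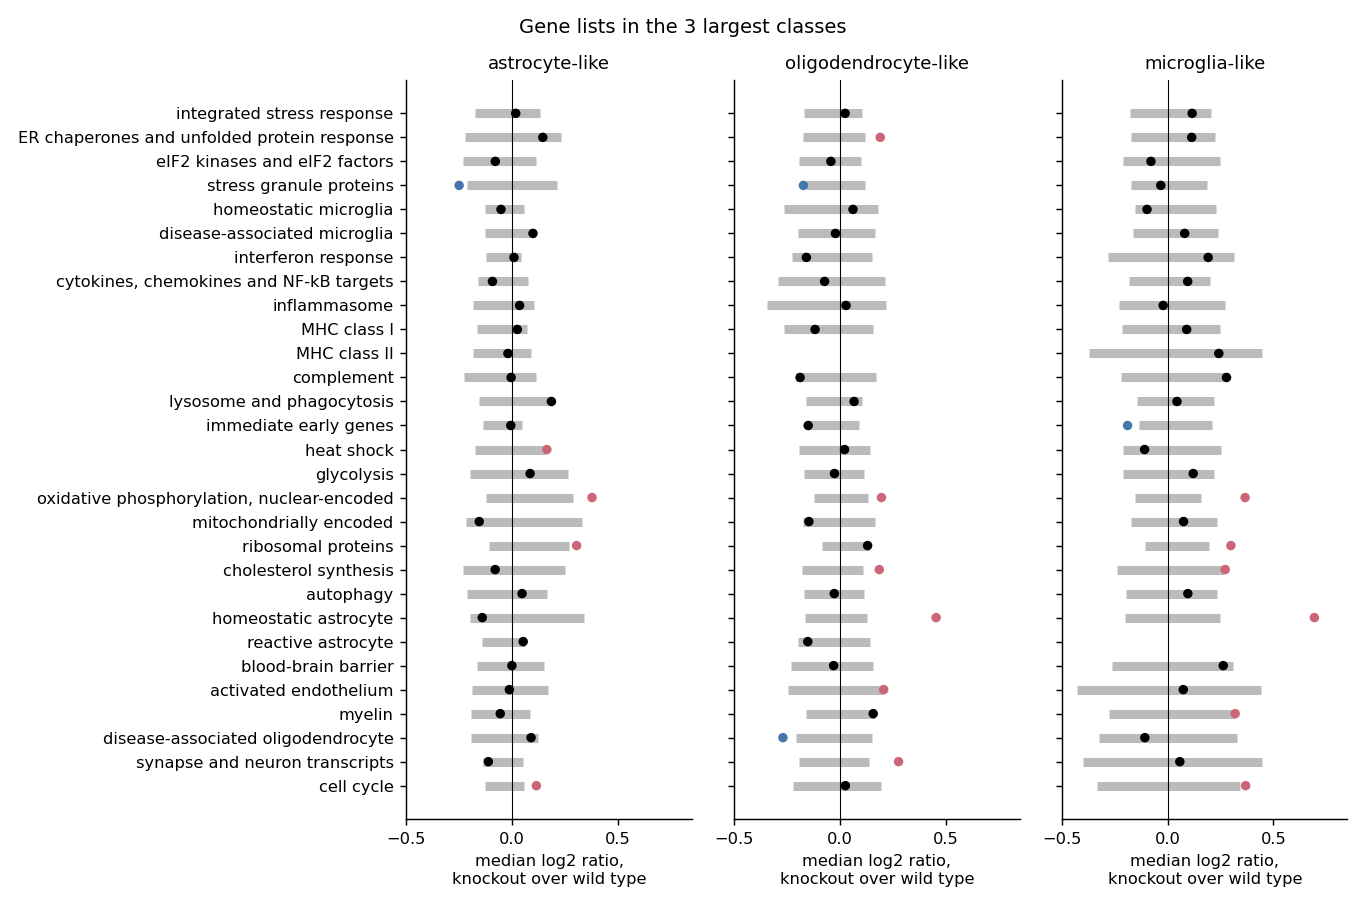
Median log2 ratio (knockout over wild type) of each gene list in the 3 largest named classes, as points; grey bars span the central 95% of 10000 matched random lists, red points lie above and blue points below that span, a missing point marks under 3 measured members, and hemoglobin is left out. Oxidative phosphorylation lies above its bar in each class, at 0.38, 0.20 and 0.37.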

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

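Restricting to cells with at least 5000 UMIs, removing the gene-length trend and taking astrocyte-like cluster 1 or 2 alone were chosen after the data were seen, and all other alternatives beforehand. No paired analysis was possible because each genotype was 1 pool without a matched partner. Of 2430 alternative values, 2260 kept the direction of the main value. By spread, 2041 stayed within that of the main value, 374 moved outside it with no established direction lost, and 15 reversed a direction that counting or resampling had set. Of those that moved, 210 moved toward 0. Outside the values given below, 301 moved, of which 264 kept their direction. The log2 ratio of Dipk1c over all cells was -0.65, and -0.62 with no filter and -0.66 with doublets kept. Some settings gave no value for classes that were not found, the member filters apply to lists alone and the cluster settings to astrocyte-like cells alone. Depth limits classes with few cells and genes with few UMIs, and thinning left 1902 UMIs per astrocyte-like, 7556 per oligodendrocyte-like and 916 per microglia-like cell. The cause of each difference was not tested.

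With no filter on genes or mitochondrial share, the log2 share ratio went from 0.34 to 0.22 for astrocyte-like, -0.15 to 0.13 for microglia-like and -0.05 to -0.57 for oligodendrocyte-like cells. In astrocyte-like cells the ribosomal median went from 0.31 to 0.26 and hemoglobin from -1.30 to -0.90. In oligodendrocyte-like cells homeostatic astrocyte genes reversed from 0.46 to -0.42 and synapse genes from 0.28 to -0.0212, activated endothelium went from 0.21 to -0.48 and hemoglobin from -1.66 to -0.65. In microglia-like cells myelin reversed from 0.32 to -1.23, and hemoglobin went from -2.93 to -2.80.

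With at least 1000 genes and at most 10% mitochondrial UMIs, share ratios became 0.24 for astrocyte-like, -0.47 for microglia-like and -0.39 for oligodendrocyte-like cells, and reversed from -0.84 to 0.69 for dendritic cell-like and from 0.30 to -0.0463 for neuroblast-like cells. Hemoglobin became -0.57 in astrocyte-like cells and -0.32 in microglia-like cells, and reversed to 0.10 in oligodendrocyte-like cells, where homeostatic astrocyte genes became 0.19. In microglia-like cells oxidative phosphorylation went from 0.37 to 0.31 and cholesterol synthesis from 0.27 to 0.00138.

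With doublets kept, the neuroblast-like share ratio reversed to -0.0728. In oligodendrocyte-like cells disease-associated genes went from -0.27 to -0.12 and hemoglobin to -0.10. In microglia-like cells immediate early genes went from -0.19 to -0.37, cholesterol synthesis to 0.53 and myelin to 1.04, and Ccl2 reversed from 1.65, with 10 CPM added on both sides, to -0.52.

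At Leiden resolution 0.5 the share ratio became 0.13 for astrocyte-like cells and reversed from 1.06 to -0.10 for monocyte-like cells, while in astrocyte-like cells the ribosomal median became 0.24 and cell cycle went from 0.12 to 0.0215. At resolution 2 the dendritic cell-like share ratio reversed to 0.85.

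With the class from each cell's own marker score, the share ratio became 0.63 for astrocyte-like cells and reversed to 0.18 for dendritic cell-like cells. Hemoglobin became -0.34 in astrocyte-like, -1.04 in oligodendrocyte-like and -0.71 in microglia-like cells. In microglia-like cells oxidative phosphorylation became 0.21, and cholesterol synthesis reversed to -0.17, homeostatic astrocyte genes from 0.69 to -0.0636 and myelin to -0.24.

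With 3000 variable genes the oligodendrocyte-like share ratio became -0.69. In that class homeostatic astrocyte genes reversed to -0.14, activated endothelium became -0.22, synapse genes 0.13 and hemoglobin -2.33, and microglia-like hemoglobin became -1.70.

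With the TMM factor, astrocyte-like oxidative phosphorylation went from 0.38 to 0.52, ribosomal proteins to 0.44 and hemoglobin to -1.16, and oligodendrocyte-like oxidative phosphorylation from 0.20 to 0.23. With the median ratio, these were 0.48 and 0.41 for oxidative phosphorylation and ribosomal proteins in astrocyte-like cells and 0.25 for oxidative phosphorylation in oligodendrocyte-like cells. With the total without mitochondrial and ribosomal protein genes, microglia-like hemoglobin was -2.92.

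Where each cell weighs the same, astrocyte-like oxidative phosphorylation became 0.26, ribosomal proteins 0.0366, cell cycle 0.0145 and hemoglobin -2.61. Synapse genes became 0.19 and hemoglobin -1.40 in oligodendrocyte-like cells, and hemoglobin -0.97 in microglia-like cells.

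With cells thinned to 1 depth, hemoglobin became -1.18 in astrocyte-like, -1.46 in oligodendrocyte-like and -1.47 in microglia-like cells. In microglia-like cells oxidative phosphorylation became 0.29, ribosomal proteins went from 0.30 to 0.39 and homeostatic astrocyte genes became 0.36.

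With a pseudocount of 1 CPM, astrocyte-like cell cycle became 0.31, astrocyte-like Dipk1c went from -0.68 with 10 CPM added to -0.81, against -0.83 with none added, and oligodendrocyte-like synapse genes became 0.58. With all detected members, synapse genes in that class became 0.0510.

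In cells with at least 5000 UMIs, astrocyte-like oxidative phosphorylation became 0.42 and hemoglobin -0.77, and microglia-like myelin 0.0311 and hemoglobin -3.89.

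With the gene-length trend removed, ribosomal proteins became 0.24 in astrocyte-like and 0.0894 in microglia-like cells, oxidative phosphorylation 0.11 in oligodendrocyte-like and 0.22 in microglia-like cells, and immediate early genes -0.41 in microglia-like cells.

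In astrocyte-like cluster 1 alone, oxidative phosphorylation was 0.0773 and ribosomal proteins 0.0707. In cluster 2 alone they were 0.0725 and 0.0813, and hemoglobin was -0.40.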

Other observations

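Neuroblast-like cells (196 wild-type and 343 knockout cells) lay in 2 clusters, one of them led by the cell cycle genes Cenpf, Top2a and Mki67. Interferon-response genes were lower in the knockout library there (0 of 11 higher, median -1.70, percentile 0), with Bst2 at 53.8 CPM in the wild-type and 1.47 in the knockout library and Isg15 at 36.8 and 1.26. The amino acid synthesis gene Asns was 26.6 and 54.1, and the cyclin gene Ccnd1 62.6 and 20.3. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.30 (25 of 25 higher, percentile 100) and ribosomal protein genes 0.24 (29 of 30, percentile 99.5; 0.17 and within the random range without the gene-length trend), and synapse genes one of -0.38 (10 of 12 lower, percentile 0.0200). The 18 stress granule genes had a median of -0.15 (13 lower, percentile 2.43). Of 28 lists, 3 lay above and 8 below the random range, where 1.4 lists of unrelated genes would fall outside by chance. Furthest above lay MHC class II genes (4 of 4 higher, median 1.62), all possible free RNA. Transcripts of other cell types were lower along with the interferon list, with medians of -0.43 for homeostatic astrocyte genes (9 of 11 possible free RNA) and -0.44 for myelin genes (11 of 11), and astrocyte transcripts held 0.217% of the UMIs of this class in the wild-type and 0.142% in the knockout library.

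Endothelial-like cells (169 wild-type and 262 knockout cells) held less of the leukocyte adhesion gene Vcam1 in the knockout library (243 CPM in the wild-type and 78.7 in the knockout library) and of the venular chemokine receptor gene Ackr1 (129 and 47.0). The pericyte marker Rgs5 was lower too (988 and 339), and hemoglobin held 1.93% of the UMIs of this class in the wild-type and 0.381% in the knockout library. Immediate early genes were lower (12 of 17, median -0.43, percentile 0), such as Fos (146 and 48.0), and interferon-response genes higher (12 of 16, median 0.32, percentile 99.99), such as Ifitm3 (974 and 1415), though without the gene-length trend the latter median was 0.15 and within the random range (percentile 97.47). Genes of the integrated stress response were higher in this class (7 of 8, median 0.27, percentile 98.6), with Slc3a2 at 513 and 877. Of 28 lists, 4 lay above and 2 below the random range. The list of activated endothelium lay within it (4 of 9 genes higher, median -0.05, percentile 27.7). An unnamed cluster held 369 wild-type and 19 knockout cells with median UMIs of 1073 and 1417, and a cluster mostly of 1 library may be that library, since a share ratio could turn with the setting alone, as that of dendritic cell-like cells did from -0.84 to 0.85 with more clusters.

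Of the tests that follow, both on transcript length and both on the mix of clusters were chosen after the result they address was seen. Mitochondrially encoded genes had medians of -0.16, -0.15 and 0.07 in astrocyte-like, oligodendrocyte-like and microglia-like cells, all within the random range. Without the gene-span trend these were -0.21, -0.25 and -0.18, the astrocyte-like and oligodendrocyte-like ones below the range. Nuclear-encoded respiratory chain and ribosomal protein genes had positive medians in all 3 main classes. That of the ribosomal protein list lay within the random range in oligodendrocyte-like cells. Scaling is unlikely to account for these positive medians. Median-ratio scaling moved the median of all genes by only 0.07, 0.04 and -0.02 in astrocyte-like, oligodendrocyte-like and microglia-like cells. The lowest of the 6 was 0.1832 under it. A shift of that size could hardly have brought them near 0, so this value adds no further test. Once the trend with gene span was removed 4 of the 6 stayed above the range, all 3 of the respiratory chain list but 1 of the 3 of the ribosomal protein list, so gene span is unlikely to account for the former and stays open for the latter. A trend with transcript length is a candidate explanation for the ribosomal protein list, of which 0 of 3 medians stayed above the range without that trend, while for the respiratory chain list 2 of 3 did, that of microglia-like cells only at the bound (percentile 97.53) and that of oligodendrocyte-like cells not, and the question stays open. In astrocyte-like cells at most 0.2348 of either median was left with the same mix of clusters in both libraries, so the mix may carry most of the difference. Clusters 1 and 2 were split largely by library, however, so matching on them cannot tell a mix of cells from a difference between libraries. In oligodendrocyte-like and microglia-like cells at least 0.8697 was left. The mixes there were similar to begin with. The largest cluster held 74% of wild-type and 71.1% of knockout oligodendrocyte-like cells, and 66.4% and 64.5% of microglia-like cells. The mix of these clusters is thus unlikely to account for the difference there, while cell states within them were not examined.

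Metallothionein genes and several glucocorticoid-regulated genes were also higher, with Tsc22d3 at 228 CPM in the wild-type and 366 in the knockout library in astrocyte-like cells and at 169 and 321 in microglia-like cells, though Sgk1 was lower in the latter (978 and 751). Gene span is unlikely to account for this in astrocyte-like cells, because the bin medians of that trend ran only from 0.0952 to -0.185. The lowest log2 ratio of Mt1, Mt2 and Tsc22d3 there was 0.8074 without the trend. A trend of that size could hardly have brought these ratios near 0, so this value adds no further test. Values of these genes without the transcript-length trend are not given here. A stronger glucocorticoid response in the knockout pool, from handling or from the genotype, may explain the higher levels of these genes. Glucocorticoid targets not seen among the ranked genes had a median at percentile 98.42 in astrocyte-like cells (12 of 18 higher). That median stayed above the random range without either length trend. Elsewhere the explanation stays open. The percentile was 97.81 in oligodendrocyte-like cells, but 93.56 without the gene-span trend and 99.99 without the transcript-length trend. It was 76.3 in microglia-like cells, but 94.26 without the gene-span trend and 99.6 without the transcript-length trend. It was 52.9 in neuroblast-like and 43.8 in endothelial-like cells. Mt1, Mt2, Mt3 and Kifc3 all lie on chromosome 8 between 94152607 and 95202812. Kifc3 was higher in each astrocyte-like cluster, with log2 ratios of 0.94, 1.35, 1.59 and 1.19. Whether sequence in that part of chromosome 8 differed between the pools was not tested. A difference in time of day was predicted to give the opposed arms of the clock genes medians of opposite sign, over 0.5 apart. A lower bound was set for its absence. In astrocyte-like cells both were negative, -0.18 for the output arm and -0.34 for the activator arm. They differed by 0.1624 (-0.06 to 0.45), so the prediction was not met in this class. The interval runs past the lower bound, so a weaker difference in time of day stays open. Genotype may itself underlie either pattern, and replicate pools with measured corticosterone could separate it from the pool.

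Much of the interferon difference in neuroblast-like cells may come from a few wild-type cells. Of the UMIs of these genes, 10 such cells held 81.61% in that library, against 32.9% in 10 of the knockout cells. The summed wild-type level was 347.8 CPM, and 69.3 without those 10 cells, which was still above the 45.3 of the knockout library. Sequence around the targeted locus might differ between the pools, as genes within 5 Mb lay at percentile 94.94 for the size of their differences, which leaves this open.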
